A study of Mus musculus with 2 samples.

How the data were processed

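The series holds 2 replicates of 1 group, E14TG2a mouse embryonic stem cells kept in 2i/LIF. Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was removed with Ribo-Zero Gold, and stranded libraries from total RNA were sequenced on an Illumina HiSeq 3000. The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the total of mapped fragments) with a row per gene and a column per replicate. Per the submitters' processing notes, CASAVA, TopHat2 and Cufflinks were used with the builds mm10 and GRCm38, and per the series' design text the quality-filtered reads were analysed at gene level. Versions, the annotation release, the use of strand, filters on rows and any scaling between libraries are not given in the sources used here. Columns were assigned to replicates because their names equal the description of each sample. Because Cufflinks estimates abundances, an FPKM of exactly 0 can be a failed estimate and is reported as listed at 0. None of 76 ribosomal protein genes was at 0, but Snurf, Snhg9 and Snhg14 were, and whether these are failed estimates is not known.

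Depth in reads is not known, and FPKM depends on effective transcript lengths that the table does not give. The low values were examined for whole-number steps. Of 2288 genes with a mean FPKM under 0.1 and values above 0 in both replicates, 1523 (66.6%) had a ratio between replicates within 0.01 log2 units of a ratio of whole numbers up to 8, against 14.1% for uniform ratios. The share was computed again for 501 relative worths of a read, from 0.707 to 1.41 (replicate 2 over replicate 1). It was highest, at 67.0%, for a relative worth of 1.00, against a median of 11.1% over the values tried and at most 49.0% away from the best value, so a read was worth nearly the same in both libraries. No counting interval or detection floor in reads was computed, and no count model was used. High FPKM values are more precise, as the spread between replicates by level shows in the results.

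Gene symbols were matched by stable identifier, for 28256 of 28592 genes, and 336 kept their identifier. Gene types and spans came from RefSeq on GRCm38.p6, the build named in the notes, by current symbol for 23798 genes and by an unambiguous synonym for 428 (84.7% of genes in all). The synonym rule was set after the data were examined. Another 4366 genes had no type.

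The 25 gene lists, the tests and the alternatives were fixed before the data were examined. Of 498 listed names 464 were measured under exactly that symbol. Synonyms were not used for list members, because trial matches led to other genes. That choice was made after the matches, but not their effect, were seen. Genes are named by a fixed rule: the 4 highest and 2 lowest members of each list, the 15 highest lncRNAs and the 15 highest protein-coding genes, the 5 largest and 5 smallest log2 ratios between replicates at a mean FPKM of at least 5, and Lncenc1, Pou5f1, Sox2, Nanog, Xist and Dnmt3b. Ties at 0 were resolved by list order, and 1 gene that the rule names is not reported here.

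Levels were analysed as log2(FPKM + 1), so differences understate the changes of low genes. The median of each list was placed among the medians of 10000 random lists of the same size, and the median log2 ratio between replicates among 10000 random lists matched on mean expression in 40 bins. The list median is that of the members' mean FPKM, and its SD is that of the medians of the single replicates. Where the list median lay outside the replicate medians, or 1 of these differed from it by more than 1.5 times, the replicate medians are given instead of the SD. Comparisons of lists or gene classes used a two-sided permutation test of the labels of genes on the difference of mean log2(FPKM + 1), averaged over replicates, with genes in both lists left out. Each test used 100000 resamples, with Benjamini-Hochberg adjustment over 15 comparisons at 0.05. Genes are not independent replicates, and co-regulated members make such p-values too small. For neighbours, each lncRNA was paired with the protein-coding gene nearest on the RefSeq map, and each coding gene was used once per class. The 33 genes in both classes were not left out and entered this test on both sides. The alternatives covered pseudocounts of 0.1 and 0.01, detection limits of 0.1, 0.5 and 5, ranks, rescaling to TPM, random lists drawn from detected genes, centring of the replicates and leaving out each replicate.

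The procedures were tested on simulated data built on the 28592 genes. Of unchanged pairs of lists 5.5% gave p under 0.05, and of lists moved by 3 log2 units 98.5% did. Smaller differences between lists were not simulated, so that share says nothing about comparisons that did not pass. A set of 200 genes at a mean FPKM of at least 1, doubled in 1 replicate, gave percentile 100. Its median log2 ratio of 1.00, taken without a pseudocount, only restates the doubling. The simulated noise between replicates had the same size at every level. Small shifts of short lists of low genes were therefore not tested. Of unchanged lists 96% lay within the central 95% of their random lists, and 6% of random lists exceeded the 95th percentile for level. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.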

Results

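RNA levels were measured in E14TG2a mouse embryonic stem (ES) cells, a male line deficient in Hprt, grown in 2i/LIF medium. This medium blocks MEK and GSK3 signalling and supplies leukaemia inhibitory factor, and it holds the cells in the naive ground state of pluripotency. The series has 1 group of 2 replicates, and its stated purpose was to profile long non-coding RNAs (lncRNAs) in that state. No other condition was compared, so the comparisons below set genes and gene lists against each other within this cell state. Each library was made from total RNA after ribosomal RNA depletion, with strand-specific sequencing. The table gave 1 FPKM value per gene and replicate for 28592 genes. FPKM summed to 946498 in replicate 1 and 928174 in replicate 2, and the number of reads behind them is not known. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical. Values are mean FPKM ± SD over the replicates (n = 2), and a gene was called detected at an FPKM of at least 1 in both. Gene spans are those of RefSeq on GRCm38.

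The replicates had nearly the same transcriptome. The core pluripotency factor Pou5f1 (chromosome 17, 35506032 to 35510777) stood at 1005 and 947, Nanog (chromosome 6, 122707489 to 122714633) at 267 and 269, and Dnmt1, the maintenance DNA methyltransferase, at 76.2 in both. Across genes, Pearson's r of log2(FPKM + 1) was 0.997 and Spearman's rho was 0.965, computed over genes, which are not independent replicates. The SD of the log2 ratio between the replicates, on the FPKM + 1 scale, was 0.16 among detected genes. Without a pseudocount, over genes above 0 in both replicates, the median absolute log2 ratio fell with level. It went from 0.17 at a mean FPKM of 1 to 5 to 0.06 at 100 or more. The genes furthest from equality at a mean FPKM of at least 5 were Gm29163, listed at 0 in replicate 1 and at 17563 in replicate 2, Gm28872 with 0 and 96.3, ENSMUSG00000046088.8 with 0 and 32.5, Ece1 with 2.49 and 46.7, and Ccdc191 with 3.74 and 12.3. In the other direction they were ENSMUSG00000094740.1 with 72.9 and 16.3, Tmsb15l with 20.6 and 7.76, Prss36 with 16.5 and 7.38, Gm42418 with 1154 and 624, and Srd5a3 with 13.4 and 7.04. RefSeq types Gm29163 as an snRNA with a very short span (chromosome 9, 83938369 to 83938475), for which FPKM is uncertain.

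**Figure D1:**
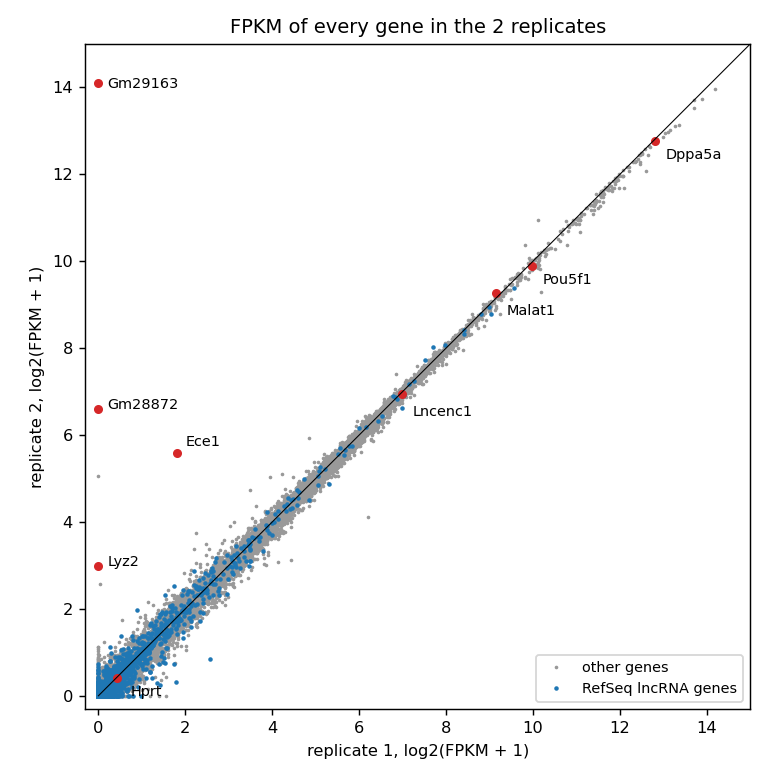
FPKM of every gene in replicate 1 (x axis) and replicate 2 (y axis), both as log2(FPKM + 1), with RefSeq lncRNA genes in blue, other genes in grey, named examples in red and the line of equality in black. Most genes lie along the line (Pearson's r = 0.997), and Gm29163, Gm28872, Ece1 and Lyz2 lie above it.

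In all, 11253 genes were detected, 39.4% of those in the table. They included 10469 of 20707 protein-coding genes (50.6%) and 311 of 3138 lncRNA genes (9.91%), as typed by RefSeq. The RefSeq protein-coding genes with the highest levels were histone, translation and ribosomal protein genes, led by Hist1h4k at 17321 ± 1966, Rpl13a at 14416 ± 1124 and Eef1a1, a translation elongation factor, at 13349 ± 98.8. Dppa5a (chromosome 9, 78367052 to 78368199), an RNA-binding protein typical of naive cells, was the only pluripotency gene among the 15 highest coding genes, at 7048 ± 107. At an FPKM of at least 100 there were 1033 genes, 17 of them typed as lncRNAs and 28 without a RefSeq type. At 1000 or more there were 145 genes, none typed as lncRNA and 8 without a type. Whether lncRNAs are among these untyped genes was not examined. Genes listed at 0 in both replicates numbered 8009, and 2611 more were at 0 in 1 replicate only.

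The pluripotency network was expressed throughout. All 15 core pluripotency factors were detected, with a list median of 80.3 ± 1.78. They were led by Pou5f1 at 976 ± 40.8, the co-repressor Trim28 at 568 ± 12.1, Zfp42 at 382 ± 7.56 and Nanog at 268 ± 1.44, with Sox2 at 168 ± 9.38 and Utf1 lowest at 4.08 ± 0.540. All 20 measured naive pluripotency factors were detected too, with a list median of 31.8 ± 0.235. Dppa5a, Zfp42, Fbxo15 (224 ± 1.48) and Tcl1 (154 ± 1.83) were the highest of them, and Klf5 (9.57 ± 1.32) and Tfap2c (8.60 ± 0.304) the lowest. Both list medians exceeded those of all 10000 random lists of the same size (percentile 100).

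Naive factors were set against markers of the primed epiblast, the later pluripotent state. Of 24 primed markers 14 were detected, with a list median of 4.21 ± 0.171 (percentile 98.1 among random lists, and 78.6 for its detected members among random lists of detected genes). The highest were Igfbp2 at 349 ± 41.0, the Nodal antagonists Lefty2 at 193 ± 26.7 and Lefty1 at 78.3 ± 16.3, and the ERK-responsive factor Etv5 at 131 ± 5.06. Fgf5, a growth factor of the primed epiblast, was at 0.0488 ± 0.0210, and Cer1 was listed at 0 in both replicates. Naive factors were higher by 2.81 ± 0.74 in mean log2(FPKM + 1) (SE over genes, 20 against 24 genes). This gave p = 0.0006 by a two-sided permutation test of list membership, and 0.0009 after Benjamini-Hochberg adjustment over 15 comparisons. The members of a list are genes, not replicates, so this p and those that follow describe the lists within these libraries.

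Markers of the germ layers and of trophectoderm were mostly below detection. In the ectoderm list 2 of 15 genes were detected, Tubb3 (31.2 ± 0.646) and the neural progenitor filament Nes (9.24 ± 0.224), and the list median was 0.0321 ± 0.00912. The mesoderm list had 1 of 15, the transcription factor T at 12.4 ± 0.733, and a median of 0.0808 (0.0443 and 0.0994 in replicates 1 and 2). The endoderm list had 1 of 15, the laminin gene Lama1 at 16.2 ± 0.366, and a median of 0.124 (0.0468 and 0.119 in replicates 1 and 2), with Cxcr4 as the only other member above 1 in replicate 2 (1.24). The trophectoderm list had 4 of 15, the keratins Krt8 (14.9 ± 0.781) and Krt18 (1.97 ± 0.108), Rhox6 (2.06 ± 0.480) and Cdx2 (1.29 ± 0.240), and a median of 0.225 ± 0.0173. Dlx5, Msgn1, Nkx2-5, Ttr, Tpbpa and Prl3d1 were listed at 0 in both replicates. Naive factors were higher than each of these lists, by 4.94 ± 0.63 over ectoderm, 5.18 ± 0.56 over mesoderm, 5.12 ± 0.57 over endoderm and 4.92 ± 0.58 over trophectoderm markers (difference of mean log2(FPKM + 1) ± SE over genes). In each of these permutation tests p was 1e-05, the smallest that 100000 resamples can give, and 1.9e-05 after adjustment. With a pseudocount of 0.01 the differences were 8.99, 8.84, 8.73 and 8.31 in the same order, since most markers lay near 0.

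Of 18 feeder fibroblast markers 4 were detected, Vim at 270 ± 12.6, Sparc at 53.3 ± 3.68, Fn1 at 45.7 ± 1.02 and Fbln1 at 19.13 ± 0.933. The intermediate filament gene Vim and the matrix genes Sparc and Fn1 stood above the naive list median of 31.8. The list median was 0.0981 in replicate 1 and 0.487 in replicate 2, and 15 of the 18 genes were higher in replicate 2. Its median log2 ratio of replicate 2 to replicate 1, on the FPKM + 1 scale, was 0.13 (percentile 99.98 among random lists matched on level). Naive factors were higher than these markers by 4.06 ± 0.78 (permutation p = 1e-05, adjusted 1.9e-05), and by 6.73 with a pseudocount of 0.01. In the other direction, Wnt target genes had a median log2 ratio of -0.10 between the replicates (percentile 0.34), with 5 of 17 higher in replicate 2. The remaining lists of the 25 lay within the central 95% of their random lists. With 25 lists, about 1 would be expected outside that range by chance, and no test between single libraries is possible.

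Markers of the rare state resembling 2-cell embryos were low, with 4 of 13 detected and a list median of 0.210 over members' means, and of 0.344 and 0.258 in replicates 1 and 2. Those detected were Zscan4f (5.58 ± 1.30), Zscan4c (4.92 ± 0.277), Zscan4d (2.55 ± 0.0201) and Gm5662 (2.49 ± 0.463). The Zscan4 genes are near-identical copies, so the division of reads among them is uncertain.

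Target genes of the pathways that 2i/LIF acts on were compared next. LIF/STAT3 targets had the highest list median, 11.3 ± 0.449, with 13 of 16 detected (percentile 99.5, and 48.8 among detected genes). They were led by Tfcp2l1 (69.3 ± 0.417), Pim3 (39.6 ± 4.01), Pim1 (33.0 ± 2.90) and the receptor subunit Il6st (32.4 ± 1.33). Fos (0.385 ± 0.106) and Cish (0.117 ± 0.0587) were the lowest of this list. Its members Tfcp2l1, Stat3, Klf4, Klf5 and Gbx2 also belong to the naive list, so the 2 lists are not independent. MEK/ERK targets had 10 of 18 detected and a median of 1.36 ± 0.0949. Within them Etv5 was at 131 ± 5.06, the cyclin gene Ccnd1 at 55.9 ± 0.887 and Etv4 at 16.3 ± 0.185, while the feedback inhibitor Spry4 was at 0.124 ± 0.0337 and the immediate-early gene Egr1 at 0.0215 ± 0.0218. Wnt/beta-catenin targets had 9 of 17 detected and a median of 1.29 ± 0.240, with Notum at 49.9 ± 3.14, Axin2 at 19.4 ± 1.51 and Sp5 at 12.9 ± 2.34, against Lgr5 at 0.0171 ± 0.00779 and Wnt8a at 0.00844 ± 0.0119. Wnt and MEK/ERK targets, without the genes in both lists, differed by 0.0062 ± 0.67 (15 against 16 genes, permutation p = 0.99, adjusted 0.99). The sign of that difference turned in replicate 2 alone (-0.03) and with a pseudocount of 0.1 (-0.10), and neither value passed the test.

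Regulators of chromatin were expressed and most Hox genes were not. Of 13 genes of the DNA methylation machinery 12 were detected, with a median of 19.9 ± 0.359 (percentile 99.8, and 82.1 among detected genes). Uhrf1, the cofactor of Dnmt1, was at 249 ± 0.322, the imprint-protecting factor Zfp57 at 169 ± 0.808, Dnmt1 at 76.2 ± 0.00622 and the de novo methyltransferases Dnmt3b and Dnmt3a at 21.6 ± 0.0732 and 4.69 ± 0.451. Of 20 Polycomb components 19 were detected, with a median of 23.3 ± 0.754, led by Mtf2 (221 ± 8.50), Rbbp7 (202 ± 3.62), Eed (117 ± 2.63) and Rbbp4 (93.3 ± 5.76). Of 37 Hox genes 3 were detected, Hoxc12 (4.32 ± 0.716), Hoxc13 (3.55 ± 0.272) and Hoxc4 (1.42 ± 0.285), and the Hox median was 0.0911 ± 0.00814. Hoxd11 and Hoxd12 were among 9 Hox genes listed at 0 in both replicates. Polycomb components were higher than Hox genes by 4.21 ± 0.47 (permutation p = 1e-05, adjusted 1.9e-05), and by 6.39 and 7.86 with pseudocounts of 0.1 and 0.01.

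Genes of energy metabolism were among the most abundant. All 21 glycolysis genes were detected, with a median of 227 ± 5.39, led by Gapdh (2075 ± 56.8), the pyruvate kinase gene Pkm (1606 ± 20.6), Aldoa (1322 ± 75.5) and Pgk1 (830 ± 6.24), and with the isoforms Aldoc (13.8 ± 0.0352) and Eno2 (4.46 ± 0.405) lowest. All 26 oxidative phosphorylation genes were detected, with a median of 193 ± 2.06, led by Atp5b (3293 ± 177), Cox7c (1792 ± 3.02), Cox4i1 (1088 ± 51.7) and Cox5b (806 ± 10.8), and with Sdhc lowest at 63.7 ± 1.03. The mean log2(FPKM + 1) of glycolysis genes differed from that of oxidative phosphorylation genes by -0.67 ± 0.60 (permutation p = 0.25, adjusted 0.27), which did not pass the test, although the list medians had the opposite order. On mean ranks the difference did pass, at -3.58 percentile points (permutation, adjusted p = 0.018), and without Gapdh, Pgk1 and Sdha it was -1.02 (adjusted permutation p = 0.092). Of 18 housekeeping genes 17 were detected, with a median of 229 ± 9.38. The exception was Hprt, the purine salvage gene in which this line is deficient, at 0.336 in each replicate.

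Genes listed as imprinted covered a wide range. The lists name the parental allele that such genes are known for expressing, and alleles were not told apart in these cells. Of 18 maternally expressed genes 11 were detected, with a median of 3.92 ± 0.624 (percentile 95.7, but 94.9 in replicate 2 alone and 92.5 among detected genes). The lncRNAs of the Dlk1-Meg3 domain led them, Rian (chromosome 12, 109603945 to 109661716) at 503 ± 10.2, Mirg at 88.5 ± 3.84 and Meg3 (chromosome 12, 109540996 to 109571729) at 54.4 ± 2.28, with the ubiquitin ligase gene Ube3a at 59.7 ± 0.555 between the last pair. H19 and Slc22a3 were listed at 0 in both replicates. Of 24 paternally expressed genes 12 were detected, with a median of 1.14 ± 0.108, led by Impact (80.0 ± 1.56), Snrpn (17.4 ± 0.118), Inpp5f (9.52 ± 0.431) and Rtl1 (9.23 ± 0.527). Ins2 and Snurf were listed at 0, and Snurf lies within the span of Snrpn, so the division of reads between this pair is uncertain. The span of Rtl1 overlaps those of Meg3 and Rian, members of the maternal list. Whether strand was used in the quantification is not given, so the level of Rtl1 is uncertain too. Paternally expressed genes differed from maternally expressed ones by -1.41 ± 0.74 in mean log2(FPKM + 1) (permutation p = 0.05, adjusted 0.062), which did not pass after adjustment.

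**Figure D2:**
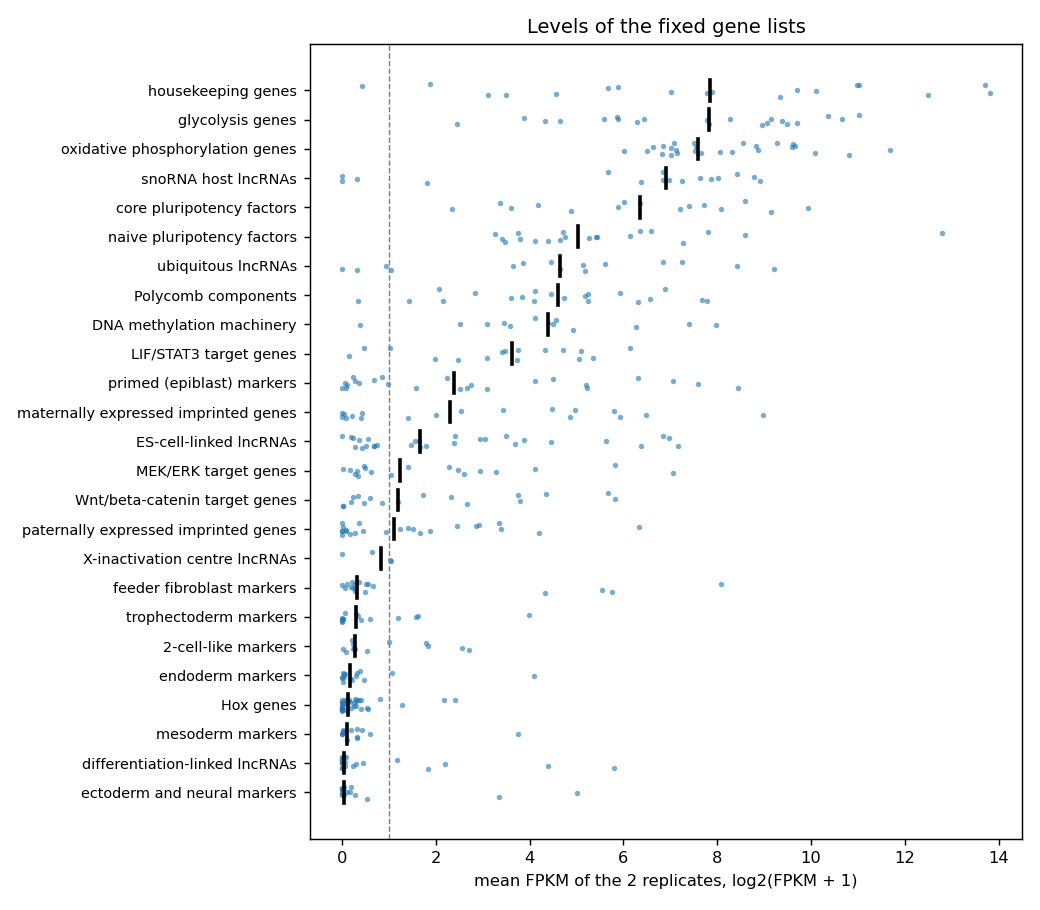
Mean FPKM over the 2 replicates, as log2(FPKM + 1), of each measured member (blue points) of the 25 fixed gene lists, ordered by list median (black bars), with an FPKM of 1 as the dashed line. Metabolic, housekeeping, snoRNA host and pluripotency lists stand at the top, and germ layer, Hox and differentiation-linked lncRNA lists at the bottom.

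The lncRNAs, the subject of the series, were fewer and lower than coding genes. The highest of those typed as lncRNAs by RefSeq were 2410006H16Rik (chromosome 11, 62602877 to 62604806) at 715 ± 63.2 and the nuclear RNA Malat1 (chromosome 19, 5795690 to 5802672) at 589 ± 31.0. They were followed by Rian at 503 ± 10.2, Snhg20 at 482 ± 61.4, Snhg8 at 441 ± 1.97, Zfas1 at 340 ± 1.59 and 1110038B12Rik at 329 ± 14.8. The next 8 were Snhg5, Rab26os, Snhg12, Epb41l4aos, Platr14, Snhg15, Lncenc1 and Platr10, from 259 ± 10.7 down to 114 ± 2.33. The median of the 311 detected lncRNAs was 3.52, against 13.6 for the 10469 detected coding genes. Detected lncRNAs were lower by a difference of -1.34 ± 0.10 in mean log2(FPKM + 1) (permutation p = 1e-05, adjusted 1.9e-05). That difference was -0.35 among genes at an FPKM of at least 5 (adjusted permutation p = 0.04). Another 4366 genes, among them mt-Co1 and mt-Co3, had no RefSeq type, 364 of them detected, and were left out of both classes.

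**Figure D3:**
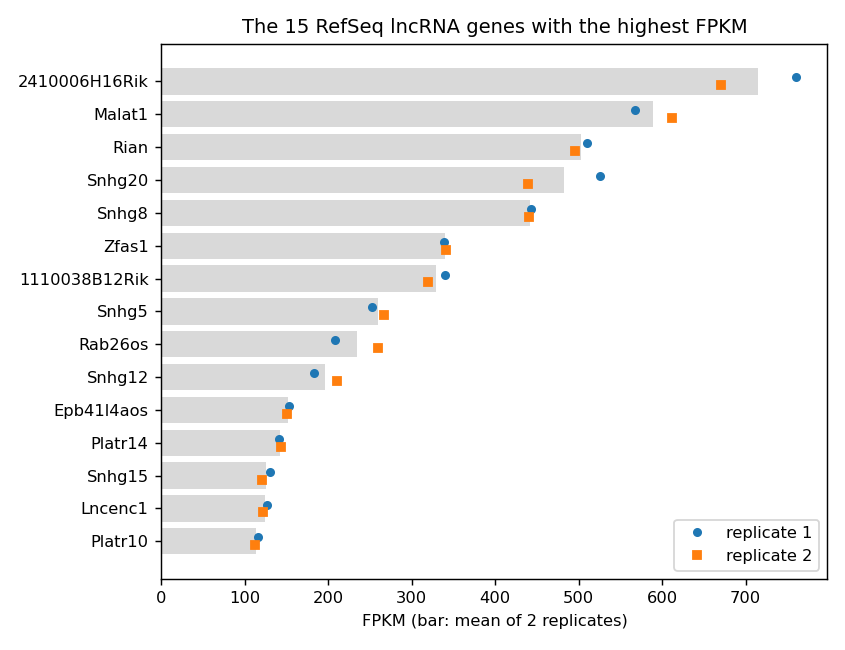
FPKM of the 15 RefSeq lncRNA genes with the highest mean, with the mean of 2 replicates as grey bars and replicates 1 and 2 as blue circles and orange squares. The genes range from 2410006H16Rik at 715 to Platr10 at 114.

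Among lncRNAs linked to ES cells, 18 of 29 were detected, with a median of 2.18 over members' means and of 2.42 and 2.43 in replicates 1 and 2 (percentile 94.98, and 96.0 and 95.7 in replicates 1 and 2 alone). The detected members lay at percentile 18.6 among random lists of detected genes. Platr14 (chromosome 2, 104559184 to 104571429) was at 142 ± 1.31, Lncenc1 (ENSMUSG00000078952.8, chromosome 13, 97434970 to 97497664) at 124 ± 2.72, Platr10 (chromosome 3, 75647441 to 75655731) at 114 ± 2.33 and the snoRNA host Snhg3 at 82.0 ± 4.05. Platr32 was at 0.141 ± 0.00138, and Platr29 was listed at 0. Of 22 differentiation-linked lncRNAs 5 were detected, Meg3, Bvht (19.9 ± 1.43), Hotairm1 (3.60 ± 0.712), Trp53cor1 (2.56 ± 0.190) and Sox2ot (1.26 ± 0.102, outside the naming rule), with a list median of 0.0363 (0.0398 and 0.0186 in replicates 1 and 2). ES-linked lncRNAs were higher by 1.73 ± 0.54 (permutation p = 0.0035, adjusted 0.0048). Restricted to members at a mean FPKM of at least 0.1, the difference was 0.53 and did not pass (adjusted permutation p = 0.6), while pseudocounts of 0.1 and 0.01 gave 3.28 and 4.86.

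Hosts of small nucleolar RNAs (snoRNAs) were the most abundant lncRNA list. Of 16 measured, 13 were detected, with a median of 120 ± 1.23 (percentile 100), led by Snhg20, Snhg8, Zfas1 and Snhg5 (259 ± 10.7), whereas Snhg9 and Snhg14 were listed at 0. Ubiquitous lncRNAs had 11 of 15 detected and a median of 24.1 ± 0.933 (percentile 99.97), with Malat1, Zfas1, Epb41l4aos (151 ± 1.77) and Gas5 (113 ± 7.10) highest and Lncpint (0.242 ± 0.222) and Jpx (0.00360 ± 0.00509) lowest. SnoRNA hosts were higher than ES-linked lncRNAs by 3.34 ± 0.96 (15 against 28 genes after Snhg3, in both lists, was left out, permutation p = 0.00055, adjusted 0.0009). On mean ranks the difference was 14.7 percentile points and did not pass (adjusted permutation p = 0.072).

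The X chromosome was examined through its coding genes and the lncRNAs of its inactivation centre. Xist (chromosome X, 103460373 to 103483233), the RNA that coats an inactive X, was at 0.558 ± 0.0614, its antisense partner Tsix at 1.03 ± 0.155, Ftx at 1.07 ± 0.128 and Jpx at 0.00360 ± 0.00509, and none of the 4 met the detection rule. Ftx exceeded 1 in replicate 1 alone (1.16) and Tsix in replicate 2 alone (1.14). Xist and Tsix overlap on opposite strands, and whether strand was used in the quantification is not given in the sources used here. Detected coding genes on the X had a median of 10.6 (372 genes) against 13.7 on the autosomes (10092 genes). Their mean log2(FPKM + 1) differed by -0.18 ± 0.11 (permutation p = 0.082, adjusted 0.094), which did not pass. The difference depended on the detection limit, being -0.33 at 0.1 (adjusted permutation p = 0.0019) and 0.0098 at 5 (adjusted permutation p = 0.99).

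Coding genes next to detected lncRNAs were more highly expressed than those next to undetected ones. The nearest coding genes of the 311 detected lncRNAs (302 genes) had a median of 12.1, and those of the 2096 lncRNAs below an FPKM of 0.1 in both replicates (1724 genes) had a median of 0.352. The difference of mean log2(FPKM + 1) was 2.01 ± 0.14 (permutation p = 1e-05, adjusted 1.9e-05), and 3.17 with a pseudocount of 0.1. Without pairs whose spans overlap, an alternative chosen after the data were seen, it was 1.61. Among the detected lncRNAs 149 overlapped their nearest coding gene, and among the others 802 did. Reads in such overlaps can be told apart only by strand.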

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

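Leaving overlapping pairs out of the neighbour comparison, counting untyped predicted genes as lncRNAs and leaving housekeeping genes out of the metabolic comparison were chosen after the data were seen, and none of these changed a call. Of the recomputed differences between lists or gene classes 81 kept their direction and their side of the threshold. A further 14 recomputed correlations, detection counts and list counts were called unchanged under the limits set for them. The count of detected genes still depended on the threshold. It was 15136 at an FPKM of at least 0.1, 12475 at 0.5 and 8021 at 5, against 11253 at 1. The other differences between lists or gene classes were as follows, and the cause was not tested. Among genes at an FPKM of at least 0.1 the X to autosome difference was -0.33 (adjusted permutation p = 0.0019), past the threshold, and at 5 it was 0.0098 (0.99), with the sign turned. On mean ranks, in percentile points, glycolysis against oxidative phosphorylation was -3.58 (0.018), past the threshold, snoRNA hosts against ES-linked lncRNAs 14.7 (0.072), no longer past it, and Wnt against MEK/ERK targets -0.83 (0.89), with the sign turned. The sign of that last comparison also turned with pseudocounts of 0.1 (-0.10) and 0.01 (-0.27), and it ranged from -0.0267 to 0.0392 when a replicate was left out, never past the threshold. Among members at a mean FPKM of at least 0.1, ES-linked against differentiation-linked lncRNAs came to 0.53 (0.6), no longer past the threshold, with fewer genes tested. The number of lists above the 95th percentile was 12, and 8 when only detected members were set against random lists of detected genes. Those lost were primed markers (percentile 78.6), LIF/STAT3 targets (48.8), DNA methylation machinery (82.1) and maternally expressed imprinted genes (92.5). Among values of single lists and genes 572 did not move beyond the replicate spread or threshold set for them, 41 moved and 1, the replicate difference of ubiquitous lncRNAs with a pseudocount of 0.1, passed its limit anew. A list percentile counted as moved only if it crossed 95, so large shifts are among the 572. Among random lists of detected genes, MEK/ERK targets went from percentile 83.05 to 8.1 and trophectoderm markers from 49.3 to 0.62. Feeder fibroblast markers rose from 48.77 to 91.74. Placements below 95 thus depended on the genes used for the random lists. Read depth is not known, and neither is how far it limits values near 0.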

Other observations

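The macrophage, fibroblast, hepatocyte, erythroid, lymphocyte, squamous, germline and S-phase lists, the gene families and all tests in this part were chosen after the data were seen, and the tests of lineage genes and of shared reads were set out after their own results had been seen.

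Several germline genes were expressed in these cells. Of 24 listed, 10 were detected, against 39.4% of all genes and 50.6% of protein-coding genes, so the list as a whole did not stand out. The highest was Rpl10l at 243 ± 11.3, a close copy of the ribosomal protein gene Rpl10 whose share of the reads is therefore uncertain. After it came the piRNA-pathway gene Tdrd12 at 81.4 ± 1.85, Tex19.1 at 50.9 ± 1.86, the X-linked homeobox gene Rhox5 at 45.7 ± 0.322, and the meiotic chromosome genes Hormad1 (24.7 ± 1.97) and Sycp3 (16.3 ± 0.464). Dazl, which also belongs to the naive list, was at 16.4 ± 0.311, whereas Tdrd1 was at 0.0471 ± 0.0197. The list median was 0.951.

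Replication-dependent histone transcripts, which lack a poly(A) tail, were abundant. Of 66 such genes 65 were detected and 50 reached an FPKM of 100, and together they held 10.5% and 9.34% of the summed FPKM of replicates 1 and 2. The 76 ribosomal protein genes held 33.1% and 31.9%. The 13 mitochondrially encoded genes held 1.64% and 1.73%, with mt-Co3 at 6474 ± 27.4. The predicted gene Gm26917 was at 6209 in replicate 1 and 4328 in replicate 2.

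Transcripts typical of macrophages and fibroblasts were higher in replicate 2. Lyz2 was listed at 0 in replicate 1 and at 6.94 in replicate 2, C1qb at 0 and 1.12, C1qa at 0 and 0.937, Col1a2 at 0.0101 and 0.917 and S100a4 at 0 and 1.17, but Fcer1g (0.0557 and 0), Cd52 (0.748 and 0.428), Cd68 (8.79 and 6.88) and Cd74 (0.283 in both) did not follow. Counting noise at low levels is argued against by a further list of macrophage genes, of which 7 of 38 are detected in these cells, since its median difference lay at percentile 99.52 of matched random lists, and a general rise of lineage genes by the 55.4% (36 of 65) of differing low lineage and Hox genes that were higher in replicate 2. A candidate explanation is a trace of RNA from macrophages and fibroblasts in replicate 2, for which 84.6% (22 of 26) of the differing low members of a further fibroblast list (12 of 38 detected) were higher there, as were 75% (21 of 28) of the macrophage list, shares at percentiles 99.91 and 98.4 of matched random lists. The same share was 33.3% (3 of 9) for hepatocyte, 62.5% (5 of 8) for erythroid, 66.7% (6 of 9) for lymphocyte and 28.6% (2 of 7) for squamous genes, at percentiles 11.3, 66.8, 70.8 and 8.60, and lists this short leave RNA from other blood cells open. Whether such RNA came from cells in the culture or from another library stays open.

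Histone and ribosomal protein genes were slightly lower in replicate 2, with 59 of 66 and 66 of 76 genes lower and median log2 ratios of -0.20 and -0.06 (percentile 0 for both among matched random lists of other genes). A smaller share of S-phase cells, as a reason for the histone genes, is argued against by 35 S-phase genes, whose median log2 ratio was -0.01 (percentile 41.8). Poorer recovery of short transcripts in replicate 2 may contribute, since 78 other coding genes with a span of at most 1500 bp and a mean FPKM of at least 5 had a median of -0.08 (percentile 0). That set left out predicted genes, genes with symbols starting Rpl or Rps and mitochondrially encoded genes, and the last of these had a median of 0.10, with 2 of 13 lower. Gene span stood in for transcript length.

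Of 8185 genes at a mean FPKM of at least 5, 48 differed more than 1.5-fold between the replicates. Predicted, pseudogene or unnamed models made up 28 of them, 6.60% of 424 such models, against 20 of 7761 other genes (0.258%). The odds ratio was 27.3 (95% interval 14.7 to 51.7, Fisher's exact p = 2.7e-24). Reads shared between overlapping or near-identical models may be involved. Overlap and likeness of the models were not measured, so this test cannot decide for that cause. Fewer reads in short models also stays open, and Gm29163 is such a short model. A further check, that 3 of the 48 exceeded an FPKM of 100 (Gm10139, Gm42418 and Gm29163), was set aside after its result was seen, because FPKM without transcript length is no read count.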
